A study of Mus musculus with 9 samples.

How the data were processed

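RNA of sorted mouse spleen Tregs was profiled by sequencing in 9 samples, 3 each of ST2-low, ST2-high and ST2KO cells. The groups come from the genotype labels and sample titles. Each deposited file holds whole-number counts per gene symbol for 1 sample, with no normalization, judged from the values and file headers. The aligner, genome build, annotation, counting tool, library kit, strand setting and sorting protocol used by the authors are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes could have been split between them by the authors' counting. How reads of near-identical copies, such as Hspa1a and Hspa1b or Tubb2a and Tubb2b, were shared out is not given either. The values of such genes are therefore uncertain.

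Each file had 23420 rows. In 27 of them the symbol had been turned into a calendar date, as spreadsheet software does with gene families named for March and September. These rows, between 0.182% and 0.206% of the counts of a library, were left out of tests and library sizes. The ribosomal RNA precursor Rn45s took between 12.1% and 16.9% of the counts. Total counts per sample were 19084575, 19150744 and 20098456 for ST2-low replicates 1, 2 and 3, 29320699, 17258535 and 16223242 for ST2-high, and 43406680, 16142473 and 11659659 for ST2KO. Intervals from counts would cover counting error only.

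Counts were normalised with TMM factors and filtered with filterByExpr by group (minimum count 10, minimum total count 15), which left 12219 genes; 6642 had no count in any library. Of the tested symbols, 93.2% were found in the RefSeq gene table of GRCm38.p6, which was used for older symbols and for neighbours only. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust glmQLFit on all 9 samples, 1 coefficient per group, no covariates) with Benjamini-Hochberg adjustment over all tested genes at 0.05. Levels are CPM with TMM factors, given as mean ± SD with n = 3, and folds are those of the edgeR fit. Lists of genes were fixed before the data were examined. Of 34 lists, 31 had at least 5 tested members and were tested with camera on voom values with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusting over the 31 lists. No member of the list of mitochondrially encoded genes was found in the rows used here, and the mast cell and basophil list and the stroma and endothelium list had 3 tested members each.

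Named genes followed a rule fixed before the data were examined: Il1rl1; in each comparison the 10 largest rises and 10 largest falls among genes past the threshold, with groups that do not overlap and a mean of at least 10 CPM in the higher group, leaving out predicted gene models, pseudogenes and receptor segments; up to 4 members of each list with the smallest adjusted p and at least 1 CPM; and any member of the Treg identity and effector Treg lists. Values of a few genes that the rule names are not reported here. Xist and Y-linked genes served as a check for mixed-up samples. Samples of a group differed beyond sampling noise in every pair (chi-square per gene between 5.12 and 23.9, the Rn45s row included), so each was counted as 1 replicate.

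The fit was tested on simulated data drawn from the real means, library sizes and dispersions over 12219 genes, with 200 genes changed. Most simulated genes were thus unchanged. In the real data, 62.3% of genes were called in ST2KO against ST2-low and 64.5% in ST2KO against ST2-high. The simulated shares need not hold in that setting. For ST2-high against ST2-low, 49.3% of genes changed by 1.25-fold, 59.7% by 1.5-fold and 78.8% by 2-fold were recovered, with 8 of 143 calls on unchanged genes. For ST2KO against ST2-low the shares were 50.8%, 76.1% and 83.3%, with 10 such calls of 159, and for ST2KO against ST2-high 41.8%, 76.1% and 93.9%, with 9 of 162. A first requirement that 80% of all 2-fold genes be recovered was not met for ST2-high against ST2-low; the misses lay at low counts, and the requirement was then set, after that result, on genes at 5 CPM or more, of which 100% of the 2-fold genes were recovered in each comparison. A spiked list was called and 0 of 30 unchanged lists were called in each comparison. The simulated genes were drawn independently of each other, so this does not show how camera treats lists of correlated genes. In the real data the estimated correlation was 0.779 for ribosomal protein genes in ST2-high against ST2-low.

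Alternatives planned before the data were examined were DESeq2 size factors, upper-quartile normalization, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, no filter, a filter of 5 CPM in 3 samples, only the 6 samples compared, the replicate number as a block, each replicate left out, a minimum fold of 1.5 with glmTreat, and windows of 10 and 5 Mb for neighbours. Leaving out Rn45s and thinning all libraries to the shallowest were added after seeing the data.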

Results

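Gene expression was measured by RNA sequencing in regulatory T cells (Tregs) sorted from mouse spleen. Tregs are the Foxp3-expressing CD4 T cells that restrain immune responses. ST2 is the receptor for interleukin-33 and is encoded by Il1rl1. The series concerns ST2-expressing Tregs in kidney inflammation and fibrosis after ischemic injury, and its labels divide the samples into 3 groups of 3: wild-type Tregs with low ST2 (ST2-low), wild-type Tregs with high ST2 (ST2-high) and Tregs of the genotype ST2KO. Total counts ranged from 11659659 in ST2KO replicate 3 to 43406680 in ST2KO replicate 1. The wild-type libraries held between 16223242 and 29320699 counts. The labels do not say whether the replicates came from separate animals. The p-values of single genes therefore rest on the spread between these samples, which may be technical. Camera compares the members of a list with other genes, and Fisher's exact test below counts genes, which are not independent replicates.

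Il1rl1 followed the sort in the wild-type groups. It stood at 2.62 ± 0.84 CPM in ST2-low and at 494.7 ± 66 CPM in ST2-high (mean ± SD, n = 3 each). In the libraries labelled ST2KO it stood at 67.6 ± 14 CPM (n = 3), which was 13.7% of the ST2-high level and 25.5-fold above ST2-low. The ST2KO libraries held 2658, 1050 and 1022 Il1rl1 counts. Counts per gene do not show which exons the reads came from, so these values do not check the knockout label, and ST2KO stands below for the libraries so labelled. Foxp3, the transcription factor that defines Tregs, was at 461.6 ± 16.3 CPM in ST2-low, 567.7 ± 47.8 CPM in ST2-high and 430.2 ± 17.6 CPM in ST2KO. Y-linked genes had counts in all 9 libraries, and Xist averaged 0.0686, 0.12 and 0.0996 CPM in ST2-low, ST2-high and ST2KO. The first principal component held 61.4% of the variance and separated ST2KO from both wild-type groups. The second held 16.25% and separated ST2-high from ST2-low.

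**Figure D1:**
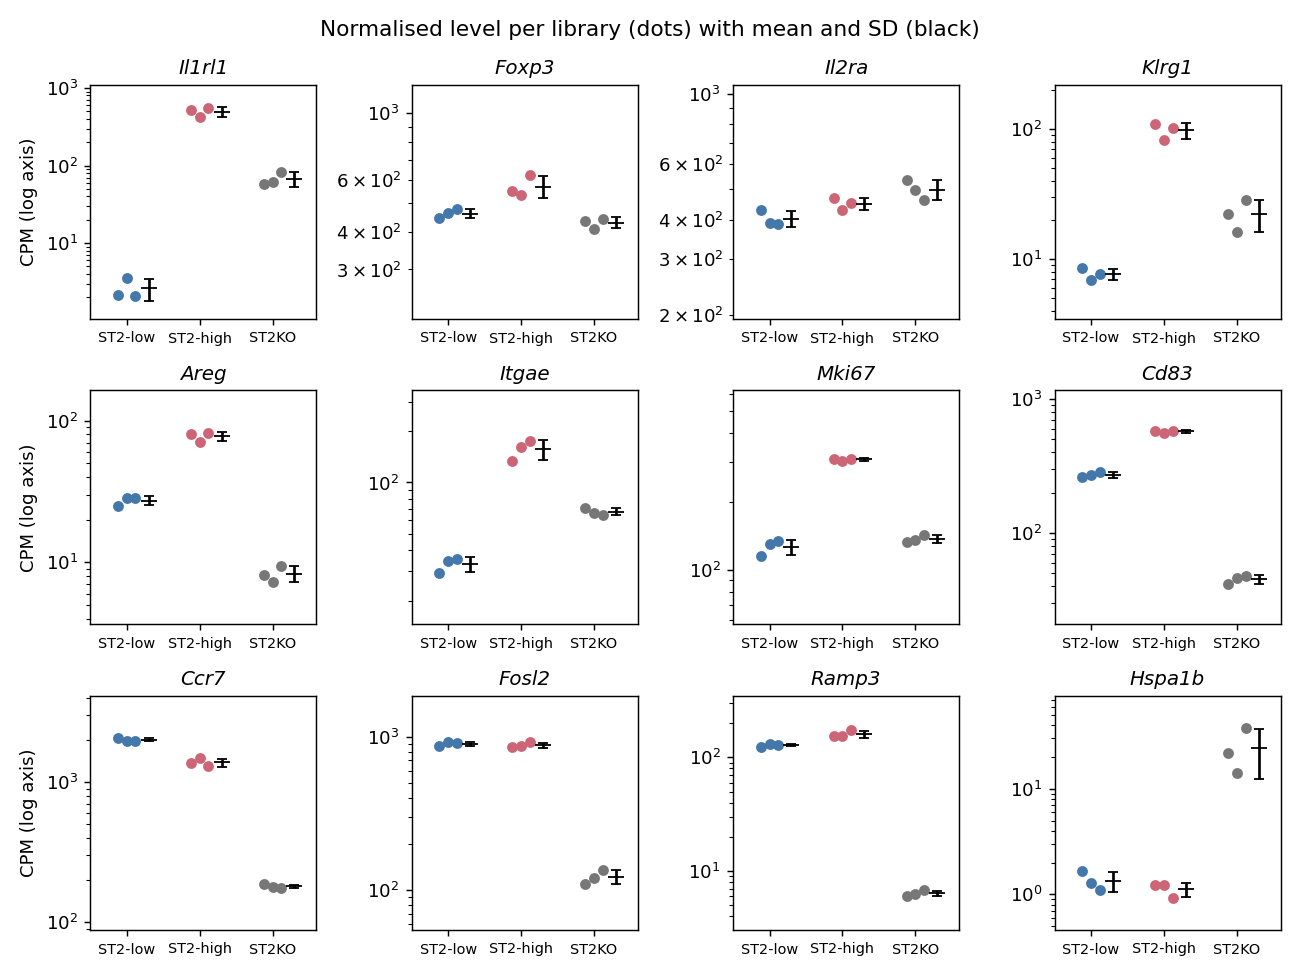
Normalised level (CPM, log axis) of 12 genes in the 9 libraries, with 3 dots per group for the replicates and black marks for the mean and SD. Il1rl1 averages 2.62 CPM in ST2-low, 494.7 CPM in ST2-high and 67.6 CPM in ST2KO, and Ccr7 averages 180.2 CPM in ST2KO against 2004 CPM in ST2-low.

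The comparison of ST2-high with ST2-low asked how Tregs that carry the receptor differ from those that carry little of it. ST2-high Tregs had more transcript of effector Treg, cell division and NF-kB response genes, and less of genes typical of naive T cells. The list of interleukin-33 receptor signalling genes, which contains Il1rl1, did not pass camera (adjusted p = 0.248). Of its 25 tested members, 7 rose, 4 fell and 14 did not pass, and fry called it higher (adjusted p = 0.00101). Camera did not call it in ST2KO against ST2-low or ST2-high either (adjusted p = 0.357 and 0.086). Fry called it lower in both (adjusted p = 0.000369 and 7.23e-06). Beside Il1rl1 itself, on which the cells were sorted, the gene with the largest rise under the naming rule was Klrg1, an inhibitory receptor of differentiated lymphocytes, at 98.2 ± 14.0 CPM against 7.69 ± 0.77 CPM (12.8-fold). Ky, Nhsl2, Rhoc, Frmd5, the interleukin-9 receptor gene Il9r, the chemokine receptor gene Ccr3, the nuclear lamina gene Lmna and the transcription factor gene Zbtb46 followed, between 5.07-fold and 8.63-fold higher. The largest falls were smaller, from 2.09-fold for Syde2 and Itga9 to 1.81-fold for Ly6c1, with Ryr2, Gucy1a3, Rasl11b, Tubb2b, Scarna2, Tubb2a and Adcy6 between them.

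Of the 38 genes of tissue and effector Tregs, 34 rose in ST2-high, 0 fell and 4 did not pass; adjusted over the list alone, 34 rose and 1 fell. Prdm1, a regulator of effector differentiation, was 3.47-fold higher, S100a4 4.22-fold, S100a6 3.81-fold and Fgl2, a secreted suppressive molecule, 3.15-fold. Il10 rose 1.21-fold, and Lag3 was at 11.97 ± 2.63 CPM against 16.8 ± 2.96 CPM without passing the test, which 8 of 16 alternatives changed (edgeR, DESeq2 or limma adjusted p between 0.000313 and 0.254). Among 22 Treg identity genes, 11 rose, 6 fell and 5 did not pass, with 11 and 6 adjusted over the list alone. The integrin gene Itgae rose 4.74-fold, the costimulatory receptor gene Icos 1.89-fold, Ikzf2 1.35-fold and Foxp3 1.23-fold, while Gpr83 was 1.63-fold lower. Ctla4 was at 2123 ± 71.4 CPM against 1996 ± 46.9 CPM and did not pass. Il2ra and Lrrc32 passed with small changes of 1.12-fold up and 1.14-fold down, and both calls were lost without ST2-high replicate 1 (edgeR adjusted p = 0.179 and 0.11) or ST2-low replicate 3 (0.165 and 0.0583). The call of Il2ra was also lost without ST2-low replicate 2 and with DESeq2 size factors, the 5 CPM filter or DESeq2's test, its adjusted p over edgeR, DESeq2 and limma alternatives lying between 0.016 and 0.179, and that of Lrrc32 between 9.92e-05 and 0.11. The Treg identity list as a whole had adjusted p = 0.0506 with an estimated correlation.

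Of 35 proliferation genes, 31 rose and 0 fell, with 32 and 0 adjusted over the list alone. Mki67 reached 307.1 ± 4.2 CPM against 125.9 ± 9.96 CPM, and Ccna2, Kif11 and Top2a rose 2.74-fold, 2.49-fold and 2.43-fold. Of 23 NF-kB response genes, 18 rose and 0 fell, with 19 and 0 adjusted over the list alone. They included Icam1 (2.31-fold), the activation marker Cd83 (2.10-fold), Nfkbie (1.84-fold) and Nfkbiz (1.80-fold). Of 22 naive and central T cell genes, 16 fell and 1 rose, with 20 and 1 adjusted over the list alone. The transcription factor genes Bach2 and Satb1 were 1.60-fold and 1.53-fold lower, and Ccr7, the lymph node homing receptor, was 1.45-fold lower. The suppressive mediator list had 15 of 23 genes higher and 2 lower, with 15 and 4 adjusted over the list alone, among them the granzyme gene Gzmb (3.42-fold higher) and Lgals1 (2.47-fold higher). Chemokine receptors and integrins had 19 of 35 higher and 4 lower, with 19 and 5 adjusted over the list alone, including Gpr55 (3.79-fold) and Itgb1 (2.02-fold). Of 19 Th1-associated genes, 8 rose and 0 fell, also when adjusted over the list alone. The interleukin-18 receptor genes Il18rap and Il18r1, which lie beside Il1rl1 in the mouse genome, rose 3.98-fold and 2.74-fold.

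Of 13 tested Th2-associated genes, a list that contains Il1rl1, 10 rose and 0 fell, with the same counts adjusted over the list alone. Ccr4 rose 2.26-fold and the transcription factor gene Gata3 1.67-fold, and the list had adjusted p = 0.0652 with an estimated correlation. Of 16 tissue repair and growth factor genes, 8 rose and 0 fell, with 9 and 1 adjusted over the list alone. Areg, the epidermal growth factor family member amphiregulin, was at 77.7 ± 5.73 CPM against 27.3 ± 2.01 CPM (2.85-fold), and the list had adjusted p = 0.139 with an estimated correlation. Of 8 tested markers of type 2 innate lymphoid cells, 4 rose and 1 fell, also when adjusted over the list alone, with adjusted p = 0.253 with an estimated correlation; Klrg1, Gata3 and Rora of that list are also on the effector Treg list. Of 54 ribosomal protein genes, 30 fell and 0 rose, with 38 and 0 adjusted over the list alone (adjusted p = 0.419 with an estimated correlation and 0.0859 with fry). The fall was smaller without ST2-high replicate 3, which stood apart from its group. Its chi-square per gene, Rn45s included, was 19.99 and 23.93 against replicates 1 and 2, and at most 9.64 in any other pair within a group. Its ribosomal protein genes summed to 18886 CPM against 22287 and 23027, and Rn45s took 16.72% of its counts against 13.01% and 12.14%. The Rn45s counts enter the chi-square, so these are not separate signs. Without ST2-high replicate 3, 16 of the 54 genes fell and 0 rose, and the median log2 fold change was -0.0957 instead of -0.175. Of 21 myeloid and dendritic markers, 8 fell and 2 rose, with 9 and 2 adjusted over the list alone. Vcam1 was at 22.2 ± 0.24 CPM against 33.0 ± 5.13 CPM, while Itgam rose 1.95-fold. This list had adjusted p = 0.34 with an estimated correlation and lost its camera call without ST2-low replicate 3 (adjusted p = 0.0601, with 0.00232 to 0.34 over its alternatives). Of 10 NK cell markers 2 fell and 0 rose (fry adjusted p = 0.0177), of 9 erythroid and platelet markers 2 fell and 0 rose, and of 9 neutrophil markers 0 passed. Camera called none of these lists in the main fit. It called erythroid and platelet markers lower without ST2-low replicate 1 (adjusted p = 0.0263). Neutrophil markers were called lower without ST2-low replicate 3 (camera adjusted p = 0.0076).

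In all, 1872 of 12219 genes were higher in ST2-high and 1317 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 386 and 45 of them by 2-fold or more. The filter of 5 CPM turned this balance, to 1456 higher and 1666 lower, and DESeq2 size factors gave 1691 and 1612. The log2 fold change of Klrg1 was 3.68 ± 0.21 (SE; edgeR adjusted p = 4.35e-06), that of Areg 1.51 ± 0.08 (edgeR adjusted p = 2.01e-15) and that of Bach2 -0.67 ± 0.05 (edgeR adjusted p = 2.78e-11), each with all 3 samples of a group on the same side of the other group. Of 31 lists tested with camera, 13 passed and 7 passed with an estimated correlation: effector Treg, naive T cell, Th1-associated, suppressive, NF-kB, proliferation, and chemokine receptor and integrin genes. With a minimum change of 1.5-fold as the tested limit, 347 genes passed instead of 3189, and 3266 passed without ST2-high replicate 3.

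The comparison of ST2KO with ST2-low set the libraries labelled ST2KO, in which Il1rl1 was 25.5-fold higher, beside the wild-type population with the least receptor transcript. The libraries labelled ST2KO had less transcript of NF-kB response genes and of the list of T cell receptor-induced and immediate early genes. They had more of interferon response and heat shock genes. These calls were lost when the correlation was estimated. The T cell receptor-induced and immediate early list and the NF-kB list then each had camera adjusted p = 0.352. Interferon response genes had adjusted p = 0.517 and heat shock genes adjusted p = 0.674 with an estimated correlation. Ccr7 was at 180.2 ± 5.51 CPM against 2004 ± 50.7 CPM (11.1-fold lower) and the AP-1 gene Fosl2 at 122.0 ± 13.1 CPM against 899.7 ± 27.4 CPM (7.41-fold lower). Ramp3, a subunit of calcitonin family receptors, fell 20.4-fold, and Gprc5a, Vps37b, the lactate transporter gene Slc16a3, Ell2, Epas1, Crem and the triglyceride synthesis gene Dgat2 fell between 12.6-fold and 7.60-fold. After Il1rl1, the largest rise under the naming rule was in the heat shock gene Hspa1b, at 24.6 ± 12.1 CPM against 1.35 ± 0.29 CPM. Zfp937, Thap2, Sp6, Mettl20, the growth factor gene Csf1, Apol8, Zfp442 and the chaperone gene Hsph1 rose between 4.32-fold and 6.14-fold.

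Of 24 T cell receptor-induced and immediate early genes, 16 fell and 5 rose in ST2KO, also when adjusted over the list alone. Nr4a3 and Nr4a1, nuclear receptors induced on antigen stimulation, were 5.64-fold and 3.31-fold lower, and Btg2 was 1.61-fold lower (list adjusted p = 0.352 with an estimated correlation). Of 23 NF-kB response genes, 17 fell and 2 rose, also adjusted over the list alone. Cd83 was 6.08-fold lower, Rel 3.36-fold and Birc3 2.23-fold, while Ltb was 2.36-fold higher (list adjusted p = 0.352 with an estimated correlation). Of 28 interferon response genes, 17 rose and 2 fell, also adjusted over the list alone, among them Usp18 (3.56-fold), Ifit2 (2.66-fold) and Ddx58 (1.70-fold), with adjusted p = 0.517 with an estimated correlation. Of 14 heat shock genes, 8 rose and 1 fell, also adjusted over the list alone, with adjusted p = 0.674 with an estimated correlation. Dnajb1 rose 1.58-fold, and the ST2KO libraries differed among themselves in Hsph1, at 273.1, 196.0 and 416.9 CPM. Of 19 unfolded protein response genes, 10 fell and 2 rose, also adjusted over the list alone, including Xbp1 (3.23-fold lower) and Hspa5 (1.66-fold lower), with adjusted p = 0.352 with an estimated correlation.

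Foxp3 did not pass the test in ST2KO against ST2-low (edgeR adjusted p = 0.117), but passed as lower with DESeq2 size factors, DESeq2's test or only the 6 samples compared (0.00664 to 0.64 over its alternatives). The genes Il2ra, Ikzf2 and Nrp1 rose by 1.23-fold, 1.17-fold and 1.58-fold. Stat5a, a mediator of interleukin-2 signalling, fell 4.74-fold, Lrrc32, the surface anchor of latent TGF-beta, 3.29-fold, Stat5b 2.59-fold and Ctla4 2.54-fold. Over the Treg identity list, 11 of 22 genes fell and 8 rose, also adjusted over the list alone, and the list did not pass camera. Effector Treg genes went both ways, with 18 of 38 lower and 12 higher, also adjusted over the list alone (adjusted p = 0.642 with an estimated correlation), and the camera call was lost without ST2KO replicate 1 (adjusted p = 0.0552; 0.0249 to 0.642 over camera's alternatives, and 0.000104 with fry, which does not compare the list with other genes). Ccr8, Rora and Tnfrsf4 fell 3.23-fold, 3.05-fold and 2.64-fold. Il9r, Klrg1, S100a4, Itgae and Fgl2, which were higher in ST2-high than in ST2-low, were also higher in ST2KO, by 3.10-fold, 2.87-fold, 2.14-fold, 2.06-fold and 1.76-fold. Of 16 tissue repair and growth factor genes, 10 fell and 3 rose, also adjusted over the list alone, including Vegfa (5.89-fold lower), Areg (3.31-fold lower) and Furin (1.83-fold lower), with adjusted p = 0.352 with an estimated correlation. Il10 fell 2.66-fold. Satb1, S1pr1 and Klf2 of the naive T cell list fell 2.52-fold, 2.42-fold and 2.17-fold, and 10 of its 22 members rose and 6 fell, also adjusted over the list alone; the list did not pass camera. Il18r1 rose 3.99-fold.

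Markers of several other spleen cell types, though not of all, were lower in the same libraries. Of 21 myeloid and dendritic markers 17 fell and 1 rose, also adjusted over the list alone, with Vcam1 at 5.76 ± 1.58 CPM against 33.0 ± 5.13 CPM and Mpeg1 at 7.55 ± 1.89 CPM against 33.8 ± 4.0 CPM (list adjusted p = 0.352 with an estimated correlation). Of 15 B cell markers 11 fell and 0 rose, also adjusted over the list alone, including Blk (2.24-fold lower), with adjusted p = 0.674 with an estimated correlation. All 5 tested plasma cell markers fell, also adjusted over the list alone, with adjusted p = 0.432 with an estimated correlation; this list contains Xbp1. Of 9 neutrophil markers 6 fell and 1 rose, also adjusted over the list alone. The list did not pass camera (adjusted p = 0.109) but passed without ST2-low replicate 3 (adjusted p = 0.0251; 0.0251 to 0.674 over its alternatives). The 3 tested mast cell and basophil markers fell, too few for camera. Of 10 NK cell markers 3 fell, 1 rose and 6 did not pass, of 6 conventional T cell markers 2 fell, 1 rose and 3 did not pass, of 9 erythroid and platelet markers 2 fell and 7 did not pass, and of 8 type 2 innate lymphoid markers 5 fell and 3 rose, each also adjusted over the list alone. None of these 4 lists passed camera, and fry called the NK cell and innate lymphoid lists (adjusted p = 0.015 and 0.00996).

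By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4030 of 12219 genes were higher in ST2KO than in ST2-low and 3577 were lower, 838 and 811 of them by 2-fold or more. The balance turned in several alternatives, such as DESeq2 size factors with 3729 higher and 3829 lower, while upper-quartile normalization gave 4648 and 3124, and the higher share ran from 48.6% to 59.8%. The log2 fold change of Ccr7 was -3.47 ± 0.06 (SE; edgeR adjusted p = 3.18e-28) and that of Hspa1b 4.16 ± 0.43 (edgeR adjusted p = 5.01e-05), with all 3 samples of ST2KO beyond all 3 of ST2-low. Of 31 lists, 10 passed camera and 0 passed with an estimated correlation. The labels give no batch, and genotype cannot be told apart from any separate handling of the ST2KO samples. They also divide only the wild-type cells by ST2 level, so genotype cannot be told apart from that selection either. With a minimum change of 1.5-fold as the tested limit, 2111 genes passed instead of 7607.

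The comparison of ST2KO with ST2-high set the libraries labelled ST2KO, in which Il1rl1 was at 13.7% of the ST2-high level, beside wild-type Tregs rich in the receptor. The labels divide only the wild-type cells by ST2 level, so genotype cannot be told apart here from the selection of ST2-high cells. Mki67, for example, averaged 136.8 CPM in ST2KO, 125.9 CPM in ST2-low and 307.1 CPM in ST2-high. Effector Treg, cell division, NF-kB and suppressive mediator genes were lower in the libraries labelled ST2KO. These calls were lost when the correlation was estimated: proliferation genes had adjusted p = 0.142 and the other 3 lists adjusted p = 0.0814 each with an estimated correlation. Areg was at 8.34 ± 1.10 CPM against 77.7 ± 5.73 CPM (9.43-fold lower), Cd83 at 45.2 ± 3.40 CPM against 572.5 ± 12.4 CPM (12.8-fold lower) and Ramp3 at 6.38 ± 0.36 CPM against 160.6 ± 11.2 CPM (25.5-fold lower). Irg1, Zbtb46, Dgat2, Dusp8, Gprc5a, Ell2, Gas2l3 and the transferrin gene Trf fell between 33.9-fold and 10.2-fold, and Il1rl1 was 7.44-fold lower. Under the naming rule, with its limit of 10 CPM, the largest rises were in Hspa1b (21.0-fold), the interferon-induced gene Usp18 (5.67-fold), Fbxl22, Apol8, Zfp937, the DNA demethylation gene Tet1, Zfp442, Pla2g4b, Fam78a and Hsph1 (4.25-fold).

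Of 38 effector Treg genes, 34 fell and 1 rose, also adjusted over the list alone (list adjusted p = 0.0814 with an estimated correlation). Rora was 7.15-fold lower, Klrg1 4.45-fold, Tnfrsf4 3.89-fold, Prdm1 2.44-fold, S100a4 1.97-fold and Il9r 1.91-fold. Itgb8 was the gene that rose, at 40.3 ± 7.03 CPM against 32.4 ± 0.98 CPM, and its call was lost without ST2KO replicate 2 (edgeR adjusted p = 0.0991), without ST2KO replicate 3 (edgeR adjusted p = 0.0577) or without ST2-high replicate 1 (edgeR adjusted p = 0.0621; 3.54e-05 to 0.0991 over its alternatives). Of 22 Treg identity genes, 15 fell and 5 rose, also adjusted over the list alone (list adjusted p = 0.0814 with an estimated correlation). Stat5a was 4.13-fold lower, Icos 3.74-fold, Lrrc32 2.89-fold, Ctla4 2.70-fold, Itgae 2.31-fold and Foxp3 1.32-fold, while Gpr83 was 2.93-fold higher. All 35 proliferation genes fell, also adjusted over the list alone (list adjusted p = 0.142 with an estimated correlation), including Top2a (2.75-fold), Kif11 (2.65-fold), Mki67 (2.25-fold) and Hmgb2 (1.94-fold).

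Of 23 NF-kB response genes, 19 fell and 2 rose. Of 24 T cell receptor-induced and immediate early genes, 15 fell and 4 rose. Both counts also held adjusted over the list alone (camera adjusted p = 0.0814 with an estimated correlation for each). Rel was 4.87-fold lower, Nfkbie 3.42-fold, Nfkb2 2.77-fold, Fosl2 7.25-fold, Nr4a3 5.15-fold and Nr4a1 3.54-fold, while Jun was 1.96-fold higher. Suppressive mediators had 16 of 23 genes lower and 4 higher, also adjusted over the list alone (adjusted p = 0.0814 with an estimated correlation), with Il10 3.22-fold and Cd274, the gene of PD-L1, 2.91-fold lower. Tissue repair genes had 11 of 16 lower and 2 higher, also adjusted over the list alone (adjusted p = 0.161 with an estimated correlation), with Furin 2.41-fold and Tgfb1 1.89-fold lower. Of 13 Th2-associated genes 12 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.196 with an estimated correlation), with Ccr8 4.79-fold lower. Of 35 chemokine receptor and integrin genes 18 fell and 9 rose, with 18 and 10 adjusted over the list alone (adjusted p = 0.0814 with an estimated correlation), with Ccr7 7.66-fold and Itgav 4.72-fold lower.

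Of 28 interferon response genes, 17 rose and 4 fell, with 17 and 5 adjusted over the list alone (adjusted p = 0.475 with an estimated correlation), including Ifit2 (2.95-fold), Ddx58 (1.84-fold) and Irgm1 (1.72-fold). Of 22 naive and central T cell genes 16 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.451 with an estimated correlation), with Treml2 2.63-fold and Als2cl 2.24-fold higher. Abundant members of this list went the other way. Ccr7, S1pr1, Satb1 and Klf2 averaged 180.2, 386, 463.9 and 310 CPM in ST2KO. In ST2-high they averaged 1382, 703.6, 763.7 and 473.1 CPM. Heat shock genes had 8 of 14 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.475 with an estimated correlation), with Hspa1a 10.98-fold and Dnajb1 1.83-fold higher. Of 54 ribosomal protein genes 21 rose and 2 fell, with 15 and 1 adjusted over the list alone (adjusted p = 0.707 with an estimated correlation and 0.172 with fry), but 7 rose and 6 fell without ST2-high replicate 3, and the camera call was lost without it (adjusted p = 0.291; 0.000133 to 0.707 over its alternatives). Of 19 unfolded protein response genes 13 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). The Th17-associated, glycolysis, fatty acid and type 2 innate lymphoid lists also passed camera, downwards, with adjusted p = 0.196, 0.215, 0.101 and 0.226 with an estimated correlation. Markers of several other cell types were lower in ST2KO here too: 17 of 21 myeloid and dendritic markers (adjusted p = 0.226 with an estimated correlation), 11 of 15 B cell markers (adjusted p = 0.54 with an estimated correlation) and 5 of 5 plasma cell markers (adjusted p = 0.317 with an estimated correlation) fell, with the same numbers adjusted over the list alone. Mpeg1 was at 7.55 ± 1.89 CPM against 29.6 ± 2.90 CPM and Cd14 at 0.489 ± 0.17 CPM against 4.18 ± 1.09 CPM. The 3 tested mast cell and basophil markers fell. Of 9 neutrophil markers 4 fell and 1 rose, of 10 NK cell markers 2 fell and 2 rose, of 6 conventional T cell markers 1 fell and 1 rose, each also adjusted over the list alone, and of 9 erythroid and platelet markers 1 fell and 1 rose, with 0 and 1 adjusted over the list alone. None of these last 4 lists passed camera, and fry called the conventional T cell list (adjusted p = 0.0128).

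By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3892 of 12219 genes were higher in ST2KO than in ST2-high and 3984 were lower, 835 and 1082 of them by 2-fold or more. Upper-quartile normalization turned this balance, to 4582 higher and 3443 lower, as did leaving out the Rn45s row, to 3971 and 3896, and the higher share ran from 43.2% to 57.1%. The log2 fold change of Areg was -3.24 ± 0.09 (SE; edgeR adjusted p = 3.41e-23) and that of Mki67 -1.17 ± 0.06 (edgeR adjusted p = 1.14e-17), with all 3 samples of ST2KO below all 3 of ST2-high. Of 31 lists, 21 passed camera and 0 passed with an estimated correlation. With a minimum change of 1.5-fold as the tested limit, 2378 genes passed instead of 7876, and 7775 passed without ST2-high replicate 3.

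**Figure D2:**
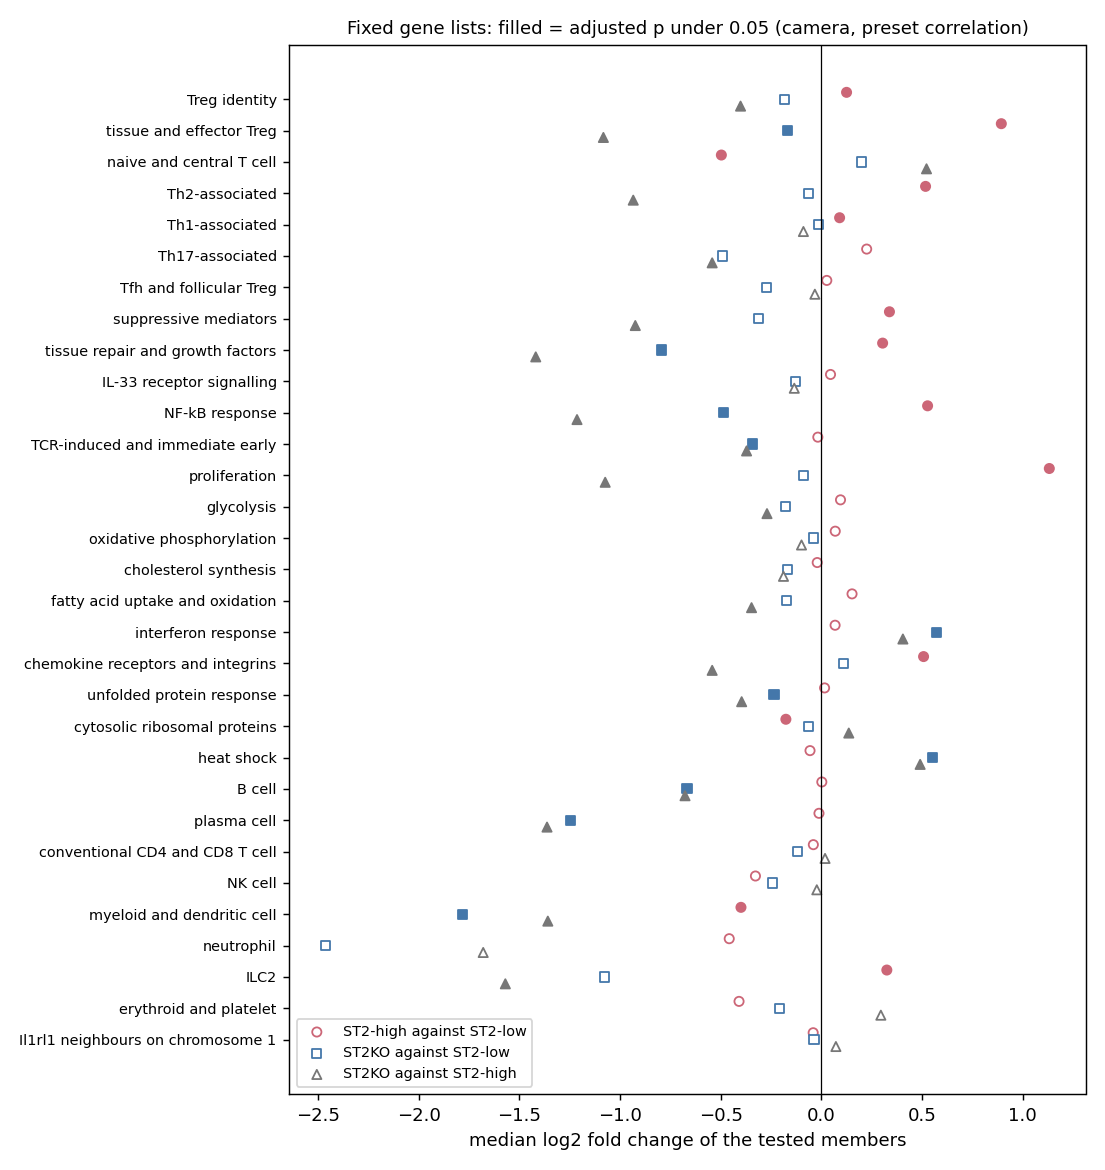
Median log2 fold change of the tested members of the 31 fixed gene lists (horizontal axis) in the 3 comparisons, with filled marks where camera with its preset correlation passed. Proliferation genes have a median of 1.13 in ST2-high against ST2-low, -0.09 in ST2KO against ST2-low and -1.07 in ST2KO against ST2-high.

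ST2KO did not sit between the wild-type populations for many genes. It was below both in 3012 genes and above both in 3129, together 6141 of 12219 or 50.3%. Of the 1872 genes higher in ST2-high than in ST2-low, ST2KO was above ST2-low in 757, such as Klrg1 and Il9r, below it in 499, such as Areg and Cd83, and did not pass against it in 616. Lists drawn independently would share 617.4 genes in the same direction and 548 in the opposite one. Of the 1317 genes lower in ST2-high, ST2KO was below ST2-low in 690 and above it in 296, against 385.5 and 434.4 for independent lists. Across genes, which are not independent replicates, the log2 fold changes of ST2KO and of ST2-high against ST2-low had r = 0.22 (Spearman's rho 0.20). Both comparisons share the ST2-low libraries. In 20 simulations of unchanged groups, r averaged 0.51 through these shared libraries, with a mean covariance of 0.0222 against the 0.0799 observed, a difference of 0.0577, and at most 1 gene was called in the same direction in both comparisons. These simulations hold no real effects. The ST2-low libraries were too few to split, so part of the overlaps may come from the shared controls.

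**Figure D3:**
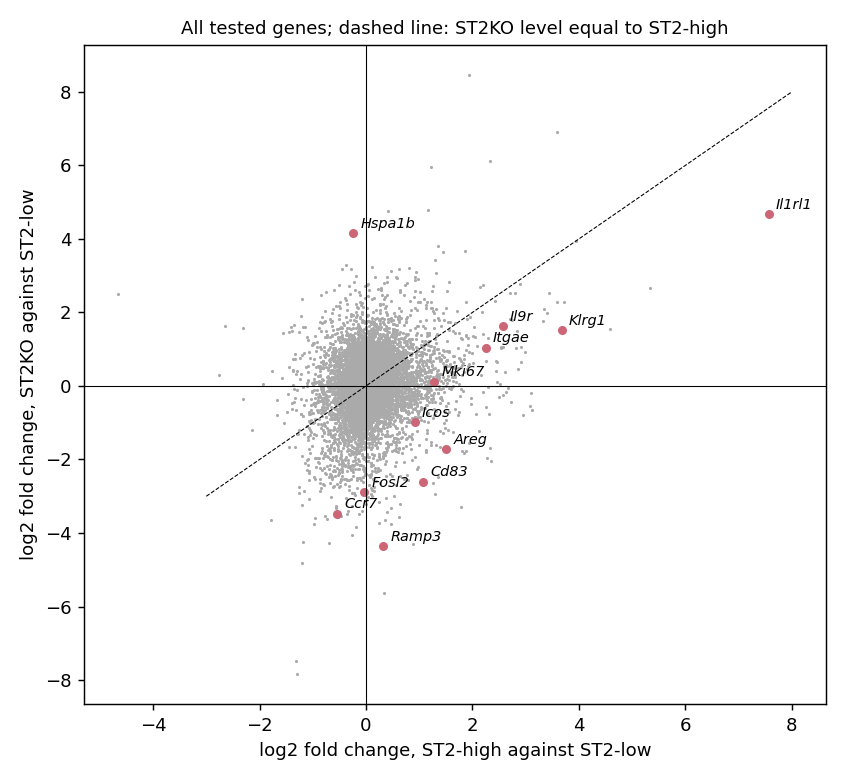
Log2 fold change of each tested gene in ST2-high (horizontal axis) and in ST2KO (vertical axis), both against ST2-low, with 12 genes named in red and a dashed line where ST2KO equals ST2-high. Klrg1 is higher in both, at 3.68 and 1.52, while Areg is at 1.51 and -1.73.

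Genes near Il1rl1 were examined because a targeted allele can carry flanking DNA of another strain. Neighbours were taken from the GRCm38.p6 gene table. Within 20 Mb of Il1rl1, 94 of 135 tested genes (69.6%) differed between ST2KO and both wild-type groups together, against 7558 of 11250 (67.2%) elsewhere. The odds ratio was 1.12 (95% interval 0.766 to 1.66; two-sided Fisher's exact test, p = 0.581). With most genes called everywhere, this count left little room for an excess near the locus.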

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

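Leaving out the Rn45s row and thinning libraries to the shallowest were chosen after seeing the data; the other alternatives were planned. The counts of changed genes stayed within 1.5 times under every scaling, test and filter run, except with a minimum fold of 1.5, which left 347 genes for ST2-high against ST2-low, 2111 for ST2KO against ST2-low and 2378 for ST2KO against ST2-high; that limit asks for larger changes by construction. Leaving out 1 library gave 2478 to 3266, 6952 to 7355 and 7127 to 7775 genes. The 5 CPM filter, which tested 9466 genes, moved the higher share in ST2-high against ST2-low from 58.7% to 46.6%. A minimum fold of 1.5 moved it to 96.5%, with 335 genes higher and 12 lower. In ST2KO against ST2-low the higher share was 53.0%; it rose to 59.8% with upper-quartile normalization and fell below 50% with DESeq2 size factors (49.3%), DESeq2's test (49.0%), the 6 samples compared (49.6%), ST2-low replicate 2 left out (49.5%) and a minimum fold of 1.5 (48.6%). In ST2KO against ST2-high it was 49.4% and passed 50% with upper-quartile normalization (57.1%) and without the Rn45s row (50.5%). The direction of either balance thus depends on the processing, and the cause was not tested. Lists past the threshold fell from 13 to 7, from 10 to 0 and from 21 to 0 with an estimated correlation, and fry, which does not compare a list with other genes, gave 24 for ST2KO against ST2-low. Fry turned the direction of naive T cell genes (adjusted p = 0.00524) and of chemokine receptors and integrins (0.000159) in ST2KO against ST2-low and of Il1rl1 neighbours in ST2KO against ST2-high (0.00967); none of these had passed camera, and the cause was not tested. The correlation of ST2KO and ST2-high changes fell from 0.22 to 0.15 with the 5 CPM filter, which tests fewer genes, and was 0.20 to 0.27 with 1 library left out. The odds ratio near Il1rl1 ranged from 0.935 to 1.14 over its alternatives, being 0.971 without ST2-low replicate 2 and 0.935 without ST2-high replicate 3 (Fisher's exact test, p = 0.532 to 1). Of 3388 values of genes chosen under the naming rule, 3353 kept direction and side of the threshold, 20 lost the call, 15 gained it and 0 reversed. Most of these genes were chosen for strong changes in these same data, so this stability was in part built in. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated between -0.063 and 0.098, and 3 of 9 samples correlated best with their own number. With the replicate block, 3210, 7622 and 7885 genes were called. Thinned to the shallowest library, 2842, 7156 and 7365 genes were called.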

Other observations

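Among the tests here, those on other spleen cells, separate handling and the Il1rl1 reads were chosen after the values they use were seen. Thinning to equal depth was also chosen after the data were seen, but its bound was written before its value was known, as were the bounds of the tests on length and GC content and on other splits of the samples.

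Of 4 genes of the Y chromosome, Ddx3y was lower and Kdm5d higher in ST2KO than in both wild-type groups, while Eif2s3y passed as lower against ST2-low and Uty as lower against ST2-high (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ddx3y was at 192.6 ± 14.4 CPM in ST2KO against 336.5 ± 17 in ST2-low and 316.9 ± 6.67 in ST2-high, and Kdm5d at 75.1 ± 8.37 CPM against 48.3 ± 5.2 and 47.6 ± 0.28 (n = 3 each). In ST2KO, ST2-low and ST2-high, Eif2s3y was at 64.8 ± 3.31, 76.2 ± 1.2 and 71.1 ± 2.93 CPM and Uty at 78.5 ± 9.36, 85.6 ± 6.62 and 89.99 ± 5.6 CPM. All 3 ST2KO values of Eif2s3y lay below those of the other 6 libraries, but its adjusted p against ST2-high was 0.0548 by edgeR.

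The first pattern is the lower level of NF-kB response and of T cell receptor-induced and immediate early genes in ST2KO. Of 47 members, 32 were below both wild-type groups and 5 above both. The median log2 fold change of the 47 members against the mean of both groups was -0.59. With every library thinned to the shallowest the median was -0.582, and 100% of the 32 members below both groups were still called lower than their mean. Thinning keeps each gene's expected share of its library, so the median could hardly move. It shows only that these calls do not need the unequal depth. After a trend on transcript length and GC content was removed the median was -0.623, which argues against length or GC bias as the whole cause. Markers of B, plasma, myeloid, neutrophil, mast and NK cells fell by 511 CPM in sum, 6.47% of the summed fall of the members. Cd74, the most abundant of those checked, was at 128.2 CPM in ST2KO and 202.3 and 228.8 CPM in ST2-low and ST2-high. Other cells in the wild-type libraries would bring their abundant transcripts with them, so myeloid, neutrophil or NK cells are unlikely to carry the pattern alone. The markers did fall, from 1129 to 618.1 CPM, and may mark a part of it. Of 12 fixed neutrophil markers 9 were tested. For B cells this sum cannot decide, since the immunoglobulin genes Ighm, Ighd, Igkc and Iglc2 of their list are not in the files. Of the 19 genes of that list 15 were tested. Plasma, mast and conventional T cells stay open: 34.8% of the fixed plasma and mast cell markers were tested, since the immunoglobulin genes of the lists are not in the files and other markers had too few counts, and of 6 conventional T cell markers 1 was higher and 2 lower in ST2KO, 9.37 CPM higher in sum. Separate handling of the libraries labelled ST2KO cannot be told apart from the genotype that the labels name, which stays open and untested, since the component that separates these libraries, with 61.4% of the variance, would arise from either.

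The second pattern is the Il1rl1 signal in ST2KO at 13.7% of ST2-high. If wild-type ST2-high cells with the levels sequenced here were the whole source, no abundant ST2-high transcript could lie at a lower part of its level. Yet 5 of 6103 genes at 20 CPM or more did so with ranges that do not overlap: Ramp3 (3.97%), Gprc5a (5.33%), Dgat2 (5.51%), Ell2 (7.1%) and Cd83 (7.9%). The limit of 5 genes for this test was set after some of these values were known and was met exactly. Cd83 and Dgat2 were below ST2-low too, at 45.2 and 2.91 CPM in ST2KO against 272.4 and 21.55 CPM. Separate handling, which stays open, could have lowered such genes in admixed cells as well. The test thus argues only against unaltered ST2-high cells as the whole source. A smaller admixture, up to the Ramp3 level, is not excluded, nor is a larger one of cells altered by handling. A mixture of the sequenced wild-type populations, unaltered by handling, would place ST2KO between them, and 6141 genes lay outside. Transcript made from the targeted allele may be the source, but counts per gene cannot show it.

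Only 10 splits of 6 samples exist, too few for a share under 0.05. The real splits called 3189 genes for ST2-high against ST2-low, 7607 for ST2KO against ST2-low and 7876 for ST2KO against ST2-high, and the highest of the other splits called 0 in each; 1 split of 10, the real one, was as large in each. The list counts were less separate. For ST2-high against ST2-low the real split passed 13 lists with camera's preset correlation and another split passed 15, so that 3 of 10 splits, the real one included, gave as many. The other comparisons passed 10 and 21 lists against highest others of 8 and 16, with 1 split of 10 as large. Camera calls with the preset correlation thus arose in regroupings in which no gene passed. Each of these regroupings mixes both groups unevenly, so it keeps part of the real difference and widens the spread within its parts. The counts are therefore not those of unchanged samples, and the camera calls in them need not be false. For ST2KO against all wild-type samples as 1 group, 6992 genes passed and the highest of the other 83 splits had 864. The real split, 1 of 84, was the only one as large, a share under 0.05 for these samples. If the replicates are technical, this shows only that the ST2KO libraries resemble each other. It does not extend to other animals or preparations.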
